A study of Clostridium acetobutylicum with 8 samples.

How the data were processed

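RNA from biofilm and planktonic cells of Clostridium acetobutylicum was hybridised to 8 one-colour Agilent arrays on 1 slide, 1 array per state and phase. The scanner software was Agilent Feature Extraction 10.7, per the submitters' processing notes. The deposited scanner files give spot brightness as intensity, on a linear scale per the file headers, with background and spatial trends removed and dim spots replaced by a surrogate value. Quality marks in the deposited files are 0 or 1 and have no other unit. The deposited value table holds log2 values, 1 per probe. Its scale and centring were found from the values, since the tool is not stated: the 8 columns had medians of 5.53 to 5.54 and shared their quartiles, and each had a correlation of 0.9985 to 0.9999 with the log2 scanner signal of its array. It had 0 columns of other samples.

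Each array had 15201 non-control spots of 8141 probes. Of these, 3687 probes carry a locus tag with coordinates, 3748 are predicted open reading frames and 706 are unnamed and spotted 11 times. Every tagged locus had 1 probe, and 155 tagged loci shared their probe sequence with another. Repeated spots gave a median SD of 0.063 to 0.090 on the log2 scale per array. No spot was saturated, and 264 to 325 spots per array were marked as uneven or deviant by the software. The number of arrays limits the precision, and no depth in counts applies.

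The detrended signal was taken to log2, spots of a probe were averaged, and the 75th percentile of the non-control probes of each array was subtracted. Loci well above background on at least 2 of the 8 arrays were tested, which left 3639. Models were fitted with limma 3.58.1 in R 4.3.3 with data.table version 1.17.8, and p-values were adjusted by Benjamini-Hochberg at 0.05. Biofilm and planktonic arrays were paired by phase, as the design text compares states of the same phase. With 1 array per state and phase, the residual of this fit, with 3 degrees of freedom, is the interaction of state and phase. As a check of the pairing, deviations from the state means were correlated across loci between the states of a phase, with r = 0.61, 0.49, 0.54 and 0.55 in the 4 phases. The contrast of the mean of phases 3 and 4 with phase 1 used the same fit. A slope of the biofilm difference over the phase number was fitted with 4 residual degrees of freedom. This fit took phase as a line without the phase block, so it did not use the pairing. Differences within a phase are values of 2 arrays with no test.

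Of 34 gene lists fixed in advance, 33 had no locus on the array, because most chromosomal loci carry another prefix and the files give no product names. Those 33 therefore gave no result. The remaining list, the pSOL1 plasmid, was tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry. Classes of locus tags and runs of neighbouring loci (same strand, gaps of at most 100 bp, at least 4 tested loci) were defined after the identifiers and before the values were seen, and were adjusted within each kind. The named runs are the 4 highest and 4 lowest per comparison among those that passed, for biofilm in 1 direction in all phases and ranked by the smallest phase difference, and the 2 highest and lowest per phase; this naming rule and the bounds of the wide chromosomal stretch were chosen after the values were seen. The plasmid segment was found from the 10 slopes with the smallest p.

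The comparisons, thresholds, first alternatives and the rule for named loci were chosen before the data were examined. By that rule, the 12 highest and 12 lowest loci across phases were named among those that passed, in 1 direction in all phases and well above background on at least 4 arrays. They were filled up, where fewer passed, by the largest smallest-of-4 difference. The rule also took the 3 highest and lowest loci measured in each phase, the 8 highest and lowest of the solventogenic comparison, and the 4 most positive and negative slopes that passed, or the 2 with the smallest p in each direction where none did. Because the files pair no tags with names, most of these loci are given by coordinates or as ranges.

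Alternatives were quantile normalization, median scaling, normexp with an offset of 50 followed by quantile normalization, the deposited value table, no filter on dim loci, only loci well above background on all 8 arrays, a trend and robust prior in eBayes, no phase block, the slide row as a covariate, each phase left out, other phase contrasts, and a 2-fold minimum. Scaling over tagged probes and a test of all probes were added after the data were seen. Random lists of loci were matched on mean signal.

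The tests were tried on simulated data of 3639 loci with 200 changed loci and the spread of the real residuals. For biofilm against planktonic cells, 59.7%, 82.1% and 90.9% of loci changed 2-, 4- and 8-fold were recovered, and 8 unchanged loci were called. For the solventogenic comparison 38.8%, 74.6% and 84.8% were recovered, with 10 unchanged loci called. For the slope the shares were 59.7%, 88.1% and 95.5% for slopes of 1, 2 and 3 on the log2 scale, with 11 unchanged loci called. With nothing planted, 0 loci were called in each. The simulated loci had no change over the phases beyond the planted one, and their spread was that of the paired fit. The slope model takes phase only as a line, so its shares can overstate the recovery in the real data. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.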

Results

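RNA was measured in Clostridium acetobutylicum, an anaerobic spore-forming bacterium that ferments sugars first to acids and then to acetone, butanol and ethanol. Biofilm cells held on a cotton fibre carrier and planktonic cells suspended in the broth were each sampled in 4 phases. These were acidogenesis at 10 h, transition at 15 h, early solventogenesis at 20 h, and late solventogenesis at 25 h for biofilm and 34 h for planktonic cells. Each state and phase gave 1 one-colour array, so the data held 4 biofilm and 4 planktonic arrays. The array carried 1 probe for each of 3687 loci with a locus tag, of which 3639 were tested. The median signal of the tagged probes was 773 to 1652 per array, against 1.85 to 4.13 for the negative controls, and 96.7% to 98.6% of the tagged probes lay well above background on each array. The number of arrays limits the precision.

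The array files pair no locus tag with a gene name, and the assembly behind their coordinates is not given in the sources used here. Loci are therefore described by their coordinates as the files give them. Loci with the prefix SMB_G run up to position 3942363 and are called chromosomal here, and loci with the prefixes CA_P, SMB_P and CEA_P share a frame that ends at 191953 and is called the plasmid. Log2 values are relative to the 75th percentile of each array. The experiment was repeated independently according to the design text, and the other run was not analysed here. Nothing in the labels says whether each array came from its own culture, so the p-values measure only the spread between these samples.

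The question of the series was which transcripts differ between biofilm and planktonic cells of the same phase. Across the 4 phases, 7 chromosomal loci rose in biofilm cells and none passed in the other direction. The highest was SMB_G0570 at 645595–645786, which was 9.81-fold higher in biofilm, a log2 difference of 3.29 ± 0.49 (SD over 4 phases; adjusted p = 0.0191). Next to each other at 680350–680778 and 680797–681417 lay SMB_G0601, 7.28-fold higher at 2.86 ± 0.38, and a neighbour on the same strand that was 6.01-fold higher at 2.59 ± 0.41 (adjusted p = 0.0191 for both). A second pair of neighbours rose at 911841–912764 and 912765–913559, by 2.11 ± 0.41 (adjusted p = 0.0389) and 2.29 ± 0.50 (adjusted p = 0.0409).

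The remaining loci that rose were at 3869827–3870261, with 2.03 ± 0.24 (adjusted p = 0.0191), and at 1748421–1748732, with 1.45 ± 0.16 (adjusted p = 0.0389). All 7 loci were higher in biofilm in 4 of 4 phases and well above background on all 8 arrays. The probe of SMB_G0570 was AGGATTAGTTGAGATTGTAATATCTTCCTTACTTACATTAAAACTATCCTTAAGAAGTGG, with a mean log2 signal of -0.003 in biofilm and -3.30 in planktonic cells. The probe of SMB_G0601 was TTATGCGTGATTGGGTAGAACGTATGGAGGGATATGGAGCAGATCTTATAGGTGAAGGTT, with a mean of 4.34 in biofilm and 1.47 in planktonic cells. Close to the locus at 3869827, the locus at 3868611–3869408 had a difference of 2.19 that did not pass (adjusted p = 0.0669). It passed with quantile normalization (adjusted p = 0.0447), within a range of 0.0267 to 0.317 over its alternatives. On the lower side, 12 loci named by the rule had differences of -1.85 to -0.95 and none passed (adjusted p = 0.0672 to 0.155). The lowest of them outside the run at 3825843 described next was at 1739076–1739972, with -1.81. It passed with median scaling (adjusted p = 0.0381), within a range of 0.0381 to 0.488 over its alternatives, and the locus at 1636743–1637759, with -1.01, passed with normexp (adjusted p = 0.0403), within a range of 0.0403 to 0.317.

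**Figure D1:**
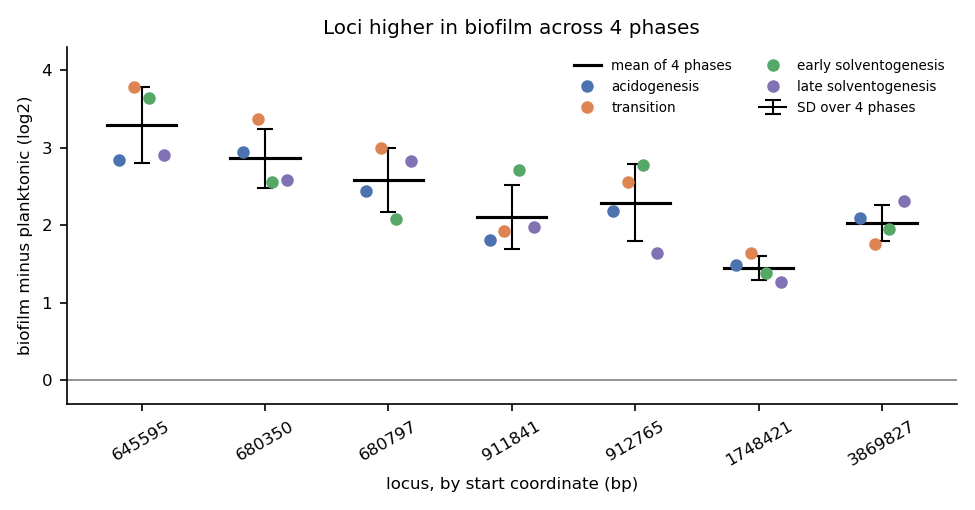
Biofilm minus planktonic log2 difference of the 7 loci that passed the test, by start coordinate. Points are the 4 phases, bars the mean, and whiskers the SD over the 4 phases; the means lie between 1.45 and 3.29, and every point lies above 0.

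The paired limma test called 7 higher and 0 lower of 3639 loci, with 666 loci at an unadjusted p under 0.05 (234 higher, 432 lower) where 182 are expected by chance. With any 1 phase left out, with the slide row as a covariate, or with all probes tested, 0 loci passed, while the differences of the 7 loci stayed between 1.32 and 3.44 over the 14 alternatives in which they were followed, which leave out the test of all probes. Under the other scalings all 7 still passed, among 12 higher and 2 lower with median scaling and 13 higher and 1 lower with normexp, and without the phase block 4 of them did. The biofilm arrays of all phases but acidogenesis and the planktonic transition array lay in slide row 1 and the others in row 2. Within a row, the 7 differences were 1.49 to 2.95 in acidogenesis and 1.64 to 3.79 in transition. The 7 loci were picked for a difference that held over these same phases. Values above 0 within a row were thus nearly fixed in advance and do not test the slide row.

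Neighbouring loci on 1 strand with gaps of at most 100 bp formed 162 runs of 4 or more tested loci, and several runs were higher or lower in biofilm in every phase. The 4 loci at 909747–913559, which include the pair named above, had phase medians of 1.42, 1.31, 1.44 and 1.79. At 370951–376334, 5 loci had medians of 2.11, 2.00, 1.03 and 2.15 (camera adjusted p = 8.1e-06; adjusted p = 0.801 with an estimated correlation). The 7 loci at 3835925–3842012 had medians of 1.08, 1.64, 0.63 and 3.04, and the 4 loci at 439414–442436 had 1.25, 4.05, 0.46 and 4.73. Ranked by the smallest of the 4 phase differences, the run lowest in biofilm was 3825843–3829980, where 6 loci had -2.53, -1.55, -0.86 and -0.86. Smaller differences in the same direction were found for 4 loci at 3217186–3221777, with an overall median of -0.71, and for 4 loci at 1885455–1889213, with -0.52. The 8 loci at 1078087–1084866 had -7.31 in acidogenesis and -0.48 to -0.67 after it; their overall median of -2.22 became -0.53 without acidogenesis.

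**Figure D2:**
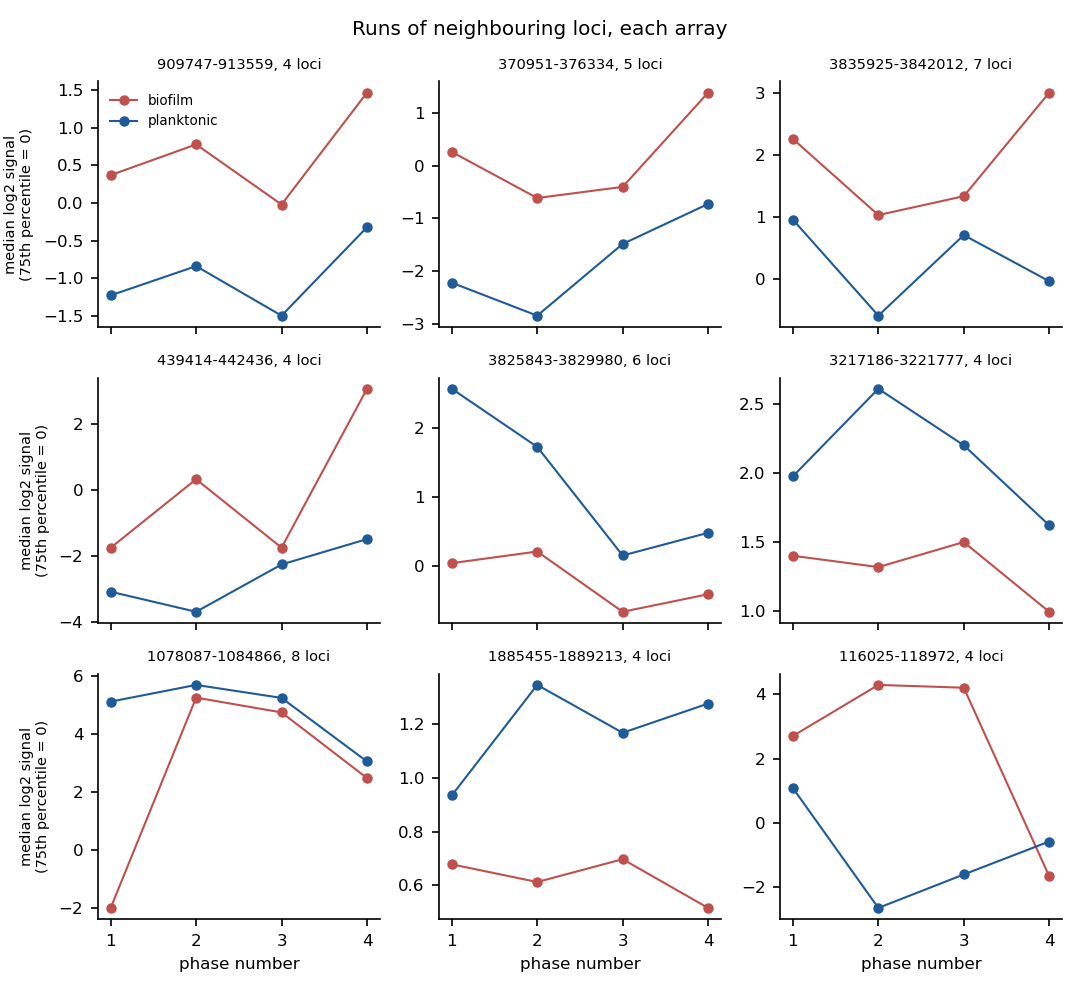
Median log2 signal of 9 runs of neighbouring loci on each array, relative to the array's 75th percentile, against the phase number (1 acidogenesis, 2 transition, 3 early and 4 late solventogenesis). Biofilm is red and planktonic blue; the run at 909747 has differences of 1.31 to 1.79 in the 4 phases, and the run at 116025 changes sign in phase 4.

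With camera at a preset correlation of 0.01, 20 runs were higher and 16 lower in biofilm, of which 10 and 15 had the same direction in all 4 phases. None passed with an estimated correlation (lowest adjusted p = 0.801 with an estimated correlation) or with fry (lowest adjusted p = 0.138). The call for the run at 1078087 was lost under 4 other scalings (adjusted p = 0.0584 to 0.0741), within a range of 0.00112 to 0.801 over its alternatives.

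Of the 3639 loci, 1058 (29.1%) differed in the same direction in all 4 phases, 337 higher and 721 lower in biofilm. Chance would give 455 if the phases were independent and their differences centred on 0. Neither held: the all-locus medians were -0.04, -0.03, 0.005 and -0.20, and the differences correlated between phases as given below. The excess and its lean to lower were therefore not tested. A difference of at least 2-fold in all 4 phases was found for 24 loci higher and 2 lower. With any 1 phase left out, which asks for fewer differences, 29 to 60 loci met this condition. In contrast, 972 loci differed 2-fold in at least 1 phase, and 97 were 2-fold higher in 1 phase and 2-fold lower in another. Across loci, which are not independent replicates, the differences of the 6 pairs of phases had Pearson's r of 0.59 for transition and early solventogenesis, 0.45 for acidogenesis and transition, and 0.10 to 0.26 for the other 4 pairs. The biofilm transition array was nearest the biofilm acidogenesis array (r = 0.964), and the planktonic transition array nearest the planktonic array of early solventogenesis (r = 0.974). Each of the other 6 arrays was nearest the other state of its own phase.

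Within single phases, which have no replicates and no test, several of the largest differences were in neighbouring loci. In acidogenesis, the locus at 1076227–1077450 and the adjacent 8-locus run at 1078087–1084866 had far less RNA in biofilm cells. The single locus had a log2 difference of -8.21 and the run a median of -7.31, from a median signal of -1.99 in biofilm and 5.13 in planktonic cells. In the transition phase both states had high signals in this run, 5.27 in biofilm and 5.71 in planktonic cells. The highest loci in acidogenesis were at 963925–964662, 964733–965419 and 3616183–3617886, with differences of 4.52 to 4.70. The last of these was 4.64, and 3.14 with the normexp background correction.

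The 4 loci at 116025–118972 were 146-fold higher in biofilm in transition and 73.8-fold higher in early solventogenesis, as medians. The transition median was 7.19 on the log2 scale, and 6.34 with normexp and 6.74 with median scaling. Their median signal was 4.29 in biofilm and -2.65 in planktonic cells in transition. The difference was 1.59 in acidogenesis and -1.02 in late solventogenesis. In transition, 15 loci at 1511864–1525054 had a median of -1.24, which was -1.69 with median scaling. The lowest loci of early solventogenesis, at 883528–884763 and 2024272–2025327, had differences of -3.51 and -3.46, which became -1.33 and -1.57 with the normexp background correction. In late solventogenesis the highest loci were 3 neighbours at 283890–285567, with 6.79 to 7.56, followed among the runs by 439414–442436 with 4.73 and 424167–429142 with 3.57. The lowest were the 5 loci at 3056059–3059545, with a median of -3.23, from -1.09 in biofilm and 2.12 in planktonic cells. Biofilm cells of this phase were sampled at 25 h and planktonic cells at 34 h.

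A wider stretch of the chromosome, 1260050–1380190, was higher in biofilm in the transition phase. Its bounds were set by a window rule chosen after the values were seen. Of its 114 tested loci, 66 were at least 2-fold higher in transition and none 2-fold lower, and they made up 19.1% of all loci 2-fold higher in that phase. The median differences were 0.42 in acidogenesis, 1.37 in transition, 0.23 in early and 0.02 in late solventogenesis. The transition median was 0.59 with the normexp background correction, where 35 of the loci were 2-fold higher, and 0.92 with median scaling, where 57 were. Its loci were dim, with a median signal of -2.09 in biofilm and -4.12 in planktonic cells in transition, and 100 of the 114 were well above background on both of these arrays.

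**Figure D3:**
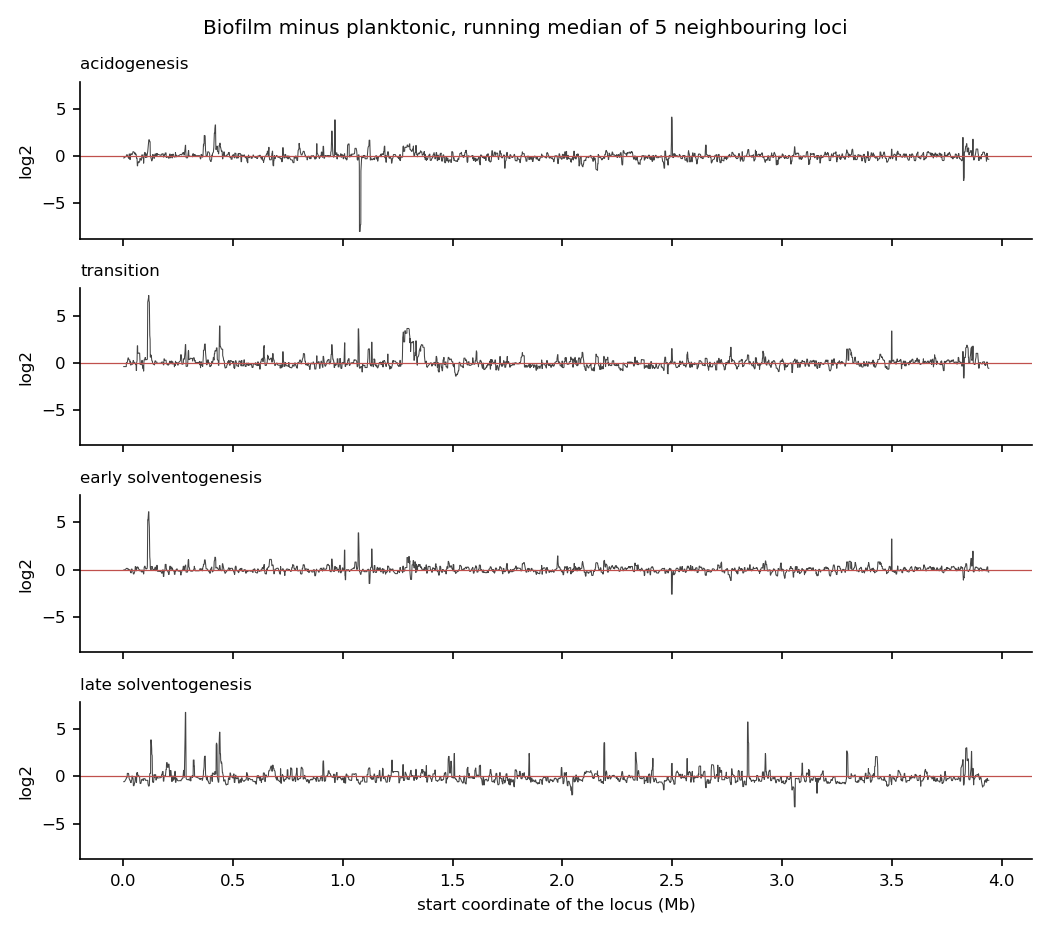
Biofilm minus planktonic log2 difference along the chromosome in each phase, as the running median of 5 neighbouring loci. The stretch at 1260050–1380190 stands above 0 in transition, where its median is 1.37, and the fall at 1078087 in acidogenesis has a run median of -7.31.

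At least 2-fold, 171 loci were higher and 148 lower in biofilm in acidogenesis, 345 and 126 in transition, 154 and 64 in early solventogenesis, and 350 and 163 in late solventogenesis. The balance in acidogenesis and transition is sensitive to the scaling. In acidogenesis it was 146 higher and 180 lower with median scaling and 173 and 183 with quantile normalization. In transition it was 227 higher and 557 lower with median scaling, which moved the all-locus median of that phase from -0.03 to -0.48, and 296 higher and 248 lower with quantile normalization. With normexp the early solventogenesis counts fell to 91 higher and 41 lower. In late solventogenesis median scaling gave 395 higher and 109 lower.

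The change from acid to solvent formation was examined by comparing early and late solventogenesis with acidogenesis in both states. Acidogenesis rested on 1 array per state, and the spread was the interaction of state and phase. Late solventogenesis was sampled at 25 h in biofilm and 34 h in planktonic cells. In the solventogenic phases 175 loci rose and 191 fell, of which 145 and 179 changed at least 2-fold. The locus at 1477693–1477977 rose 36.9-fold, a log2 difference of 5.21 (SE 0.41, adjusted p = 0.00592), and its neighbour at 1477440–1477676 rose by 4.68. A locus at 315843–316100 rose 29.1-fold (4.86, SE 0.20, adjusted p = 0.00333). The 8 highest loci lay between 3.65 and 5.21 and were higher in both states.

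Among the loci that fell, SMB_G1992 at 2077403–2077987 had a difference of -6.27, which is 77.2-fold lower (SE 0.70, adjusted p = 0.0114). Without late solventogenesis it had -3.94 and did not pass (adjusted p = 0.0747), within a range of 0.00422 to 0.0747 over its alternatives. SMB_G1154 at 1302760–1303719 had -6.24 (adjusted p = 0.0200), with 1 of its 4 solventogenic arrays well above background; it was at least 24.2-fold lower when signals below the lowest one well above background on an array were raised to it. With normexp it had -2.33 (adjusted p = 0.0589), within a range of 0.00923 to 0.0589. The locus at 1303784–1305379 next to it had -5.29 (SE 0.39, adjusted p = 0.00563), also with 1 of the 4 arrays well above background, at least 24.5-fold lower by the same bound, and -2.10 with normexp. The 8 lowest loci lay between -6.27 and -4.82 and were lower in both states, and 4 of them were well above background on all 4 solventogenic arrays. Of these 8, the loci at 1505789–1506163 and 2076868–2077401 did not pass without late solventogenesis either (adjusted p = 0.0657 and 0.0708), within ranges of 0.00408 to 0.0657 and 0.00744 to 0.0708 over their alternatives. The locus at 1299480–1300997 did not pass in 4 alternatives (adjusted p = 0.0537 to 0.0769), within a range of 0.0135 to 0.0769. With normexp it had -2.85, and the loci at 1607940–1608368 and 1608380–1608874 had -2.44 and -2.65.

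Neighbouring loci moved together in this comparison as well. All 5 loci at 2459487–2463725 rose (median 2.25), and 4 of the 5 at 2455160–2459356 (1.28), 3 of the 4 at 719147–723299 (1.99) and 5 of the 8 at 467694–477820 (1.08) did. Without late solventogenesis the last of these medians was 0.65. All 10 loci at 2151864–2161654 fell (median -3.46, and -2.18 without late solventogenesis), as did all 4 at 64672–66649 (-3.19), all 5 at 1607940–1610887 (-3.83) and 6 of the 7 at 1297449–1305590 (-4.68). The last 2 medians were -2.65 and -1.93 with normexp and -3.66 and -3.67 with dim solventogenic signals raised as above, and in the run at 1297449 only 2 of the 7 loci were measured above background on both arrays of early and of late solventogenesis. In the run at 1607940, 2 of the 5 loci were so measured in late solventogenesis. The run at 1297449 lies inside the stretch at 1260050–1380190, of whose 114 loci 37 fell and 1 rose. Camera with the preset correlation called 4 runs higher and 24 lower, none of them with an estimated correlation (lowest adjusted p = 0.960 with an estimated correlation), and fry called 5.

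**Figure D4:**
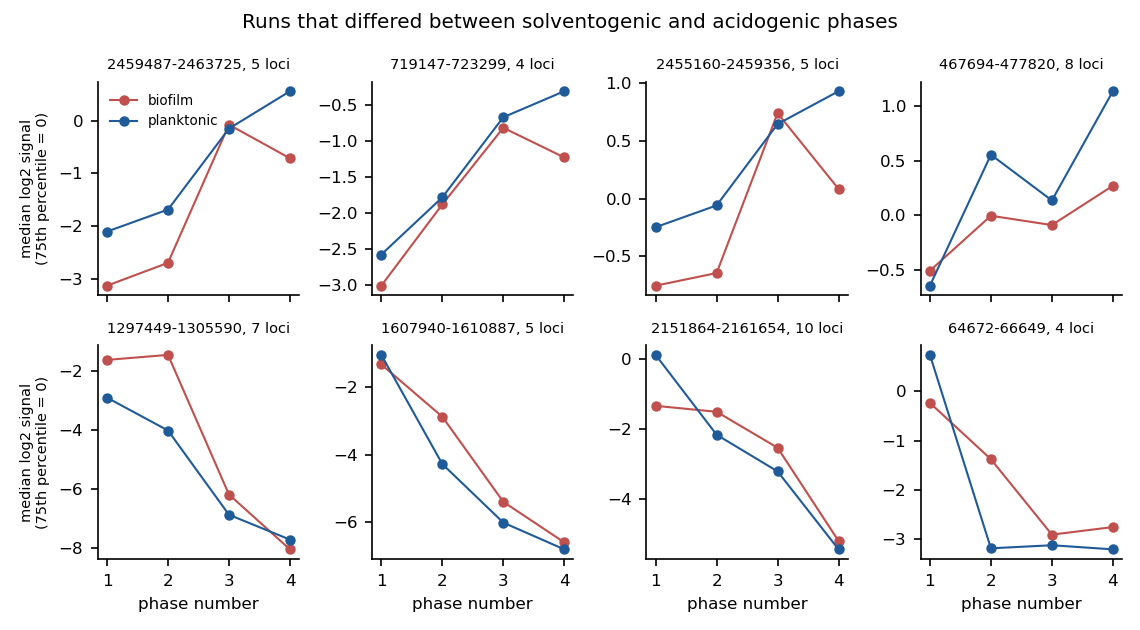
Median log2 signal of 8 runs on each array, relative to the array's 75th percentile, against the phase number, with biofilm in red and planktonic in blue. The upper runs have median solventogenic minus acidogenic differences of 1.08 to 2.25 and the lower runs of -4.68 to -3.19.

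The limma test of the solventogenic phases called 366 loci, with 1072 at an unadjusted p under 0.05. Median scaling moved the median of all loci in this comparison from 0.05 to 0.54 and gave 979 higher and 158 lower, quantile normalization gave 206 and 148, normexp 196 and 134, and the values deposited by the authors 207 and 148. Without late solventogenesis 80 loci were higher and 56 lower, and with the transition phase counted as solventogenic 131 of 238 called loci were higher.

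The pSOL1 megaplasmid carries genes for solvent formation, but none of the 7 loci of the solvent formation list was on the array by its tag. The plasmid list, the loci with the prefix CA_P, was higher in the solventogenic phases. Of its 51 tested loci, 44 were higher and 7 lower, 10 rose and none fell, and 14 rose when adjusted over the list alone. The median difference was 0.48 (camera p = 1.25e-05; p = 0.167 with an estimated correlation; fry p = 0.0133), and 0.97 with median scaling, against all-locus medians of 0.05 and 0.54. The SMB_P and CEA_P loci of the same frame had medians of 0.58 and 0.59, with 7 and 11 loci that rose and 4 and 1 that fell. Their camera adjusted p was 0.000218 and 8.4e-07, and 0.336 and 0.324 with an estimated correlation. The fry adjusted p was 0.0325 and 0.0138. Between biofilm and planktonic cells, the list's median was -0.08 and its mean -0.002, with 21 loci higher, 30 lower and none called. The camera p of this comparison was 0.884. The phase medians were -0.24 in acidogenesis, -0.32 in transition, 0.03 in early and 0.22 in late solventogenesis. The early value was -0.06 with median scaling and -0.05 with quantile normalization, and the other 3 kept their sign under every scaling tried.

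The 22 loci with r in their prefix, 117 to 2906 bp long, had median log2 signals of 8.42 to 9.53 on the 8 arrays. All 22 were lower in the solventogenic phases, with a median of -0.73 (adjusted p = 0.381 with an estimated correlation). None was called over all loci, and all 22 when adjusted over the class alone. The estimated correlation between these loci was 0.89, so counts over the class are not counts of independent loci. The median was -0.002 with quantile normalization, which gives the brightest probes of all arrays nearly the same values. Of the 65 loci with t in their prefix, 71 to 92 bp long as transfer RNA genes are, 61 were lower (median -0.58; adjusted p = 0.458 with an estimated correlation), and none was called over all loci. Their median was -0.08 with median scaling. In biofilm against planktonic cells the t-tagged loci had a median of 0.85 in transition, between 0.41 and 0.88 over the scalings, and of -0.60 in late solventogenesis. The r-tagged loci had a biofilm median of 0.15 with 22 of 22 higher (adjusted p = 0.0120, and 0.991 with an estimated correlation), which was 0.01 with quantile normalization. Their phase medians were 0.26, 0.68, 0.07 and -0.45, and at most 0.01 with quantile normalization. In transition, 7 of the 22 were at least 2-fold higher in biofilm, under the main scaling and under every other scaling tried.

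Whether the biofilm difference changed from phase to phase was tested as a slope over the phase number. Among the 10 slopes with the smallest p, the largest group was on the plasmid at 151995–156860. There, 7 loci went from a median difference of -0.82 in acidogenesis to 0.28, 1.01 and 3.42 in the later phases. In late solventogenesis their median signal was 0.59 in biofilm and -2.83 in planktonic cells, and all 7 were well above background on all 8 arrays. The planktonic median fell from 1.34 in acidogenesis to -0.36 in transition and -1.32 in early solventogenesis. Late biofilm cells were sampled at 25 h and planktonic cells at 34 h, so state and time cannot be told apart in the late value. The median slope was 1.37 per phase, and the slopes did not pass (adjusted p = 0.413). The transition median was -0.17 with median scaling. On the chromosome, the falling slopes with the smallest p were at 951219–954569, with differences of 2.70, 1.92, 1.13 and -0.09 in the 4 phases, and at 422059–422466, with 3.29, 3.20, 1.27 and 0.25. Neither passed (adjusted p = 0.413). In limma, 0 loci passed and 252 had an unadjusted p under 0.05 (173 rising, 79 falling). This fit had no phase block and did not use the pairing, and a paired fit of the slope was not made.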

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

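The tests of dim probes, of a shared time course, of scaling and of GC content in the other phases were chosen after related results were seen; the tests of spot position, of GC content in transition and of other splits were set before their values were. In 102 groups of 4 arrays, the 4 phases of 1 state, an array was checked for standing apart from the other 3. This held for 2 groups, where chance would give about 5.1 if the arrays were replicates. Phases are not replicates, and most groups were picked for their differences in the same data. The number by chance is therefore no baseline here. The run of 4 loci at 424167–429142 had a biofilm median of 2.44 in late solventogenesis against -1.75 to -1.43 in the earlier phases, a gap of 0.924 of the range. The run at 64672–66649 had a planktonic median of 0.74 in acidogenesis against -3.21 to -3.13 later, a gap of 0.979. Signals were also present in probes outside the comparisons: 434 of the 3748 predicted-ORF probes and 406 of the 706 unnamed probes lay well above background on all 8 arrays, against 0 of 77 negative control spots.

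The count of 7 loci higher in biofilm was set against other splits of the 8 arrays into 4 and 4. Of the 32 splits that the paired model could fit, 3 gave at least 7 loci, with 28 as the highest other, so this count does not exclude chance. Nor does the share measure chance. Of the 32 splits, 24 part only 2 phase pairs, and some of these keep the true states of both pairs. The 2 splits with 28 loci both hold the same contrast, the true states of transition and early solventogenesis with the other 2 phases undivided, which points to a structure of the samples; whether their count exceeds chance was not tested. The split by slide row gave 0 loci. It parts only early and late solventogenesis, along their true states, so it cannot tell slide row from state. Among the 8 splits that part every phase pair, 1 gave as many, the real one, with 0 as the highest other; 8 splits are too few for a share under 0.05.

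The stretch at 1260050–1380190 had a median difference of 1.37 in transition. A defect on 1 part of the array is argued against by the spots of its 114 loci, whose median distance lay at percentile 38.1 of random sets. Dim probes cannot be told apart as a source of its size, since the 100 loci well above background on both arrays had a median of 1.13 (bootstrap SE 0.21) against a bound of 1 and the normexp median was 0.59. Biofilm cells at an earlier point of a time course shared by both states cannot be told apart either: the median of the stretch was 1.09 higher in planktonic cells in acidogenesis than in early solventogenesis, and across the 3525 loci outside it, which are not independent replicates, the transition difference correlated with that fall at r = 0.369 (Spearman's rho 0.347). The stretch in biofilm in transition lay a median of 0.73 (bootstrap SE 0.08) above biofilm and 1.07 (bootstrap SE 0.16) above planktonic cells in acidogenesis. With normexp these medians were 0.41 and 0.52. A delay gives such a level only with a peak between the sampled times. This does not decide against a delay, because the stretch was chosen for its height on the same biofilm transition array. The bootstrap SEs measure the spread between loci of single arrays and not between samples. The state difference named by the design stays open.

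Short runs differed by over 50-fold within a phase, at 116025–118972 in transition and early solventogenesis and at 1078087–1084866 in acidogenesis. A local array defect is argued against by spot distances at percentile 37.6 or above among random sets. Over the other scalings, the smallest of the 3 medians was 5.76 in size. The runs were picked for their size in the same data, and median scaling moved the all-locus transition median only from -0.03 to -0.48. A loss of these differences was therefore hardly possible, and the test shows only that their size holds over the scalings tried. With 1 array per state and phase, a difference between the 2 samples other than their state was not tested and stays open.

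The t-tagged loci had a transition median of 0.85, with 53 of 65 higher, and -0.60 in late solventogenesis, with 62 lower. Scaling alone is argued against by a gap of 0.863 to loci matched on signal, where the highest of 1000 matched draws was 0.173. GC content cannot be told apart in transition: the t-tagged probes have a median GC content of 51.7% against 41.7% for other loci, and 361 unnamed or predicted-ORF probes between 48.3% and 56.7% GC had a median transition difference of 0.748. In 2 other phases they differed, since these probes had 0.42 in acidogenesis and -0.32 in late solventogenesis where the t-tagged loci had -0.11 and -0.60. The gaps were 0.53 (bootstrap SE 0.09) and 0.29 (bootstrap SE 0.05), with the SEs taken over probes and not over samples. The 65 loci have 40 distinct probe sequences, and a change in transfer RNA between the states was not tested.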

How the results depend on the processing

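The scaling over tagged probes and the test of all probes were chosen after the data were seen. No named locus or run that had been called changed direction. With median scaling the transition median of the plasmid segment went from 0.28 to -0.17, the early solventogenesis median of the CA_P loci from 0.03 to -0.06, the acidogenesis counts from 171 higher and 148 lower to 146 and 180, and the transition counts from 345 higher and 126 lower (471) to 227 and 557 (784). The 7 loci higher in biofilm became 14 with median scaling and 14 with normexp, 4 with no replicate block, 0 with the slide row as a covariate, 0 to 0 with 1 phase left out, and 0 when all probes were tested, where 580 tagged, 97 predicted-ORF and 62 unnamed probes had an unadjusted p under 0.05. The slide row and left-out phases leave fewer degrees of freedom; for the other changes the cause was not tested. The 26 loci 2-fold apart in all 4 phases were 29 to 60 with 1 phase left out, since fewer differences were needed. The early solventogenesis count of 218 became 132 with normexp. The 366 loci of the solventogenic comparison became 1137 with median scaling, 136 to 316 with 1 phase left out, and 238 with transition counted as solventogenic. The pSOL1 list in that comparison had p = 0.167 with an estimated correlation. The cause was not tested for these. Of 98 values of the 7 passed loci under alternatives, 60 still passed and 38 did not. Of 238 values for named loci that had not passed, 9 passed. Of 188 for named loci of the solventogenic comparison, 8 no longer passed. Of 112 and 94 values for runs, 20 and 15 no longer passed, mostly with an estimated correlation or fry. Within a phase, 13 of 112 run medians and 7 of 166 locus values moved by more than their spread. Choosing the brightest probe of a locus was not run, because each locus has 1 probe, and camera offers the variance trend but no robust prior. Loci not well above background limit the folds of the lowest signals.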

Other observations

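The 7 loci with the prefix SMB_L, in a frame of their own that ends at 10422, had median differences between biofilm and planktonic cells of -0.59 in acidogenesis and 0.26 in late solventogenesis. With the deposited value table these loci had -0.34 and 0.52, and their transition median went from -0.19 to -0.72. Across the phases their median was -0.12 and none passed in limma. In the solventogenic comparison 4 were higher and 3 lower, with none called.

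Runs that were low in biofilm in a single phase included 4 loci at 810984–815695, with a median of -0.67 in early solventogenesis and 1.04 in late solventogenesis. The 5 loci at 2459487–2463725, which rose in the solventogenic phases, had lower signals in biofilm in acidogenesis (-0.89), transition (-0.81) and late solventogenesis (-1.42) and a difference of 0.07 in early solventogenesis. The 10 loci at 2151864–2161654, which fell in the solventogenic phases, had differences of -1.45 in acidogenesis, 0.65 in transition and 0.72 in early solventogenesis, and the 4 loci at 64672–66649 had -1.05 and 1.84 in acidogenesis and transition. The 381 loci outside the stretch at 1260050–1380190 that fell at least 2-fold in planktonic cells from acidogenesis to early solventogenesis included 115 that were 2-fold higher in biofilm in transition and 14 that were 2-fold lower.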
